A study of Homo sapiens with 16 samples.

How the data were processed

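PRAISE-seq libraries of HEK293T and HuCCT1 cells were grouped by the titles of the samples into 6 groups, with 2 treated and 2 untreated HEK293T control libraries, 3 treated and 3 untreated libraries of the triple knockout, and 3 treated and 3 input HuCCT1 libraries. Nothing in the labels used here says whether libraries of one group came from separate cultures. The file analysed is a list of 13398 sites of the HEK293T map with no column per library, so no sample entered a test as a replicate. Which libraries each value was made from is not given in the sources used here.

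Per the submitters' processing notes the genome build is hg38. The aligner, the caller of deletions and the annotation tool are not given in the sources used here. The deletion level was deposited as a fraction between 0 and 1, per the file headers and the values, and is printed as a percentage. Coverage was deposited by the authors as a read count per site. The p-value and FDR of each site are those of the authors' deposited table, with no statement of the test behind them. Position, strand, the 11-nt context with the site at base 6, region, gene type and gene symbol are printed as deposited. The level times the coverage gave a whole number of deletion reads at all 13398 sites within the rounding of the level (0.0005), and these deletion reads were used for intervals. At coverage of at least 1000 this check could not fail, so deletion reads there are approximate, being the rounded product of level and coverage. All listed levels were at least 5.0%, all coverages at least 15 and all deletion reads at least 3.

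In the authors' deposited table the p-value was exactly 0 at 13242 sites and above 0 at 156, with a largest p-value of 0.000168 and a largest FDR of 0.0483. Each p-value above 0 was inverted as the upper tail of a binomial distribution to the control rate it implies. A binomial test of each site's deletion reads against a fixed background of 1% or 0.1% was run as well, with the Benjamini-Hochberg threshold of 0.05 over at least 3.86e+06 tests, the number that the ratio of FDR to p-value (288.0 to 293.6) implies.

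Gene symbols were matched to the RefSeq genes of GRCh38.p14 directly or through a unique synonym, which gave a match for 90.0% of the sites. RefSeq coordinates, which are of the same build, gave gene lengths, positions within ribosomal RNA genes and overlaps with small RNA genes. No exon structure and no genome sequence were used here, so distances to splice sites were not computed, and the RefSeq table gives no strand, so the strand of a gene could only be compared between its own sites.

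Sequence classes were assigned from the contexts in a fixed order: URUAR (PUS7 and PUS1 shared), other UNUAR (PUS7), other HRUAR (PUS1), GUUCNA (TRUB1) and uridine from 2 bases upstream to 2 bases downstream (U-tract). The design fixed before the data were examined compares sites with 10 random uridines of the same gene. Without genome sequence this was replaced, after the data and the results of several backgrounds had been seen, by 10 shuffles of the 10 flanking bases of each context. Neighbouring uridines not listed themselves, from 3 bases upstream to 2 bases downstream of the site, were tried as a background, but each shares its window with the site's own uridine, which rules out or favours a motif at most offsets, so that comparison was set aside for all classes. Mirrored motifs in the same run, each strand alone, coverage of at least 60, protein-coding genes, sites outside small RNA genes and sites past a 1% background were further alternatives chosen after the data were seen. Classes were compared with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 5 classes, and Woolf intervals. Background matched on the length of the run used the Mantel-Haenszel odds ratio, and mirrored motifs an exact binomial test. Levels were compared with two-sided permutation tests of medians (100000 resamples). Gene lists, 10 in number and fixed before the data were examined, were compared with all other RefSeq genes by Fisher's exact test, two-sided, adjusted over the lists, and with 10000 random lists of protein-coding genes matched on length in 10 bins, an alternative chosen after the data were seen.

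Sites were named by a rule fixed before the data were examined: the 10 sites of highest level, the 5 genes with the most sites, the 2 highest sites of each class and each region, and up to 4 highest members of each gene list. The part of the rule that needs knockout values could not be used. Exceptions are said to have been named after their values were seen.

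The scripts were tested on simulated data. With no motif planted, 0 of the 5 classes passed the threshold. Those contexts were themselves shuffled flanks, like the background. The check therefore covers the computation and cannot show whether shuffled flanks model real contexts. With 200 TRUB1 motifs planted among 13398 contexts, the odds ratio of that class was 6.06 and 0 other classes passed. The permutation test called 6.0% of 200 random labellings of 200 sites at the 0.05 threshold, and 98.0% after a shift of 3 points. Inversion recovered all 2000 simulated control rates from p-values at full precision. It was not tested on rounded p-values such as the deposited ones. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.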

Results

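The series maps pseudouridine, an isomer of uridine made in RNA by pseudouridine synthases, in human HEK293T cells, a transformed line derived from embryonic kidney. The assay was PRAISE-seq, in which bisulfite treatment of RNA turns pseudouridine into an adduct that reverse transcriptase skips, so that a modified position appears as a deletion in a share of the reads. The labels describe 16 libraries in 6 groups. In HEK293T these are 2 treated control libraries, 2 untreated control libraries, 3 treated libraries of cells lacking PUS1, PUS7 and RPUSD4, and 3 untreated libraries of the same knockout. In HuCCT1, a cholangiocarcinoma line, they are 3 treated libraries and 3 input libraries. The table analysed here lists 13398 sites in pre-mRNA and other transcripts on the hg38 genome, each with 1 pooled deletion level, the reads covering it, an 11-nt sequence context and an annotation. Each listed base is a uridine. Coverage was at least 15 reads with a median of 35, and the number of reads with the deletion ranged from 3 to 147089 with a median of 4. The table gives no value per library, so the levels carry no replicate error, and the intervals printed are 95% Clopper-Pearson intervals that cover counting error only.

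The map was mainly one of introns. Of the 13398 sites, 6826 were annotated as intronic (50.9%, interval 50.1 to 51.8%), 2361 as exonic (17.6%) and 1691 as lying in the 3'UTR (12.6%). Promoter regions held 1213 sites (9.05%), intergenic sequence 837 (6.25%), transcription termination regions 332 (2.48%) and the 5'UTR 138 (1.03%). Protein-coding genes held 10559 sites, long non-coding RNA genes 1370 and processed pseudogenes 642. The intronic share depended on depth, since introns were covered by a median of 29 reads and exons by 45. Among the 2655 sites with coverage of at least 60, a limit chosen after seeing the data, 28.7% were intronic and 28.6% exonic.

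**Figure D1:**
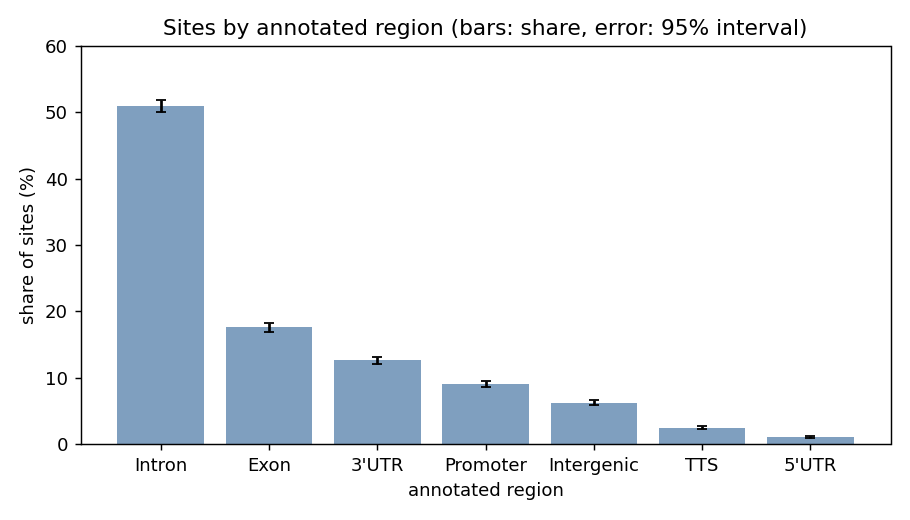
Share of the 13398 sites (y axis, percent) in each annotated region (x axis), with bars for the share and error bars for the 95% interval. Introns held 50.9% of the sites and exons 17.6%.

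The sites were spread over 7091 genes, of which 4187 (59.0%) held 1 site and 416 held at least 5. TENM1, which encodes a teneurin transmembrane protein and spans 828410 nt on chromosome X, held the most, with 45 sites, 40 of them intronic, at a median level of 12.9%. DNAH14, a dynein heavy chain gene on chromosome 1, held 24 sites, and SLIT2, which encodes an axon guidance ligand, held 18 on chromosome 4. The other genes among the 5 with the most sites were a locus deposited as 5.8S rRNA on chromosome 20 and ENSG00000280441, a non-coding gene in the ribosomal DNA of chromosome 21, with 25 sites each. Longer genes more often had a site. In the shortest decile of protein-coding genes 3.79% had one, against 45.6% in the longest decile. Across genes with a site, which are not independent replicates, the number of sites and gene length had a Spearman rho of 0.337.

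The median deletion level was 12%, with an interquartile range of 7.7 to 18.5%, and 176 sites reached 50%. The listed sites obeyed a minimum of 5% and of 3 deletion reads, so that at 15 reads no level under 20% could be listed. At the 2655 sites with coverage of at least 60, where the 5% minimum alone sets the floor, the median was 6.7%. Single levels were imprecise: 3 deletion reads in 15 give an interval of 4.33 to 48.1%, and the median width of the interval over all sites was 24.1 percentage points. Sites with exactly 3 deletion reads numbered 4931, or 36.8% of the map.

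**Figure D2:**
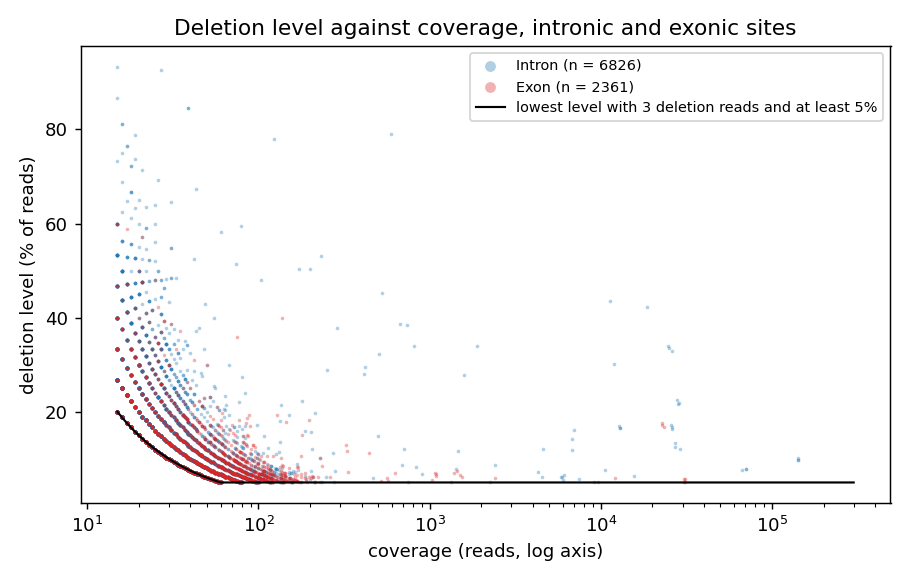
Deletion level (y axis, percent of reads) against coverage (x axis, reads, log scale) at 6826 intronic and 2361 exonic sites, one point per site. The black line is the lowest level that 3 deletion reads and a 5% minimum allow, and the points follow it down to a coverage of 60.

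The highest level stood in an intron of MED27, a Mediator subunit, at chromosome 9 position 131876192 on the minus strand, in the context ACTGCTTCTGG, with 93.3% (14 of 15 reads, interval 68.1 to 99.8%). An intron of TRRAP, a scaffold of histone acetyltransferase complexes, followed at chromosome 7 position 98893337 with 92.6% (25 of 27 reads, interval 75.7 to 99.1%). MYO9B, an unconventional myosin, had an intronic site at chromosome 19 position 17164890 with 86.7% (13 of 15 reads, interval 59.5 to 98.3%). The other 7 of the 10 highest sites lay at copies of structured RNAs, 5 at loci deposited as 5.8S rRNA or its pseudogenes and 2 at U6 pseudogenes. The sequence does not always follow that name: of the 5, the neighbouring pair on chromosome 22 and the site on chromosome 20 position 30486618 had contexts listed in the 18S rRNA, in the same register or shifted by 1 base. Outside introns, the highest 3'UTR levels were 76.4% in CELF1 (55 of 72 reads, chromosome 11 position 47470298, context TTTTTTGTTTT) and 61.9% in IGF2R (13 of 21 reads). The highest exonic levels were 60% in DNAJC3-DT and in TBC1D30, each 9 of 15 reads. In the 5'UTR, ZC3H11A reached 41.2% and NRIP1 35.0%. In termination regions, ARL1 reached 47.1% and HERC4 44.0%.

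Ribosomal RNA gave the deepest values. At position 69 of the 5.8S rRNA gene, in the context TAATGTGAATT, the 3 copies on chromosome 21 had a mean level of 55.4% at 224891 to 233963 reads, and position 55, in CTAGCTGCGAG, had 21.8%. These are positions at which human 5.8S rRNA is known to carry pseudouridine. Position 67 was listed at 9.27%. In the 18S rRNA, positions 572, 573, 918 and 1445 were listed in all 3 copies, with mean levels of 16.8%, 22.1%, 5.57% and 17.2%. The median SD between copies over the 7 positions listed in all 3 was 0.451 points. The copies are loci that can share reads, not replicates.

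Small nuclear and other structured RNAs were listed at many loci, and 166 of 351 sites of these families (47.3%) had a context listed more than once. Repeated contexts were not confined to them: 12.4% of all sites and 9.94% of protein-coding sites had one. The context TTTTTTGTTTT of the CELF1 site was listed at 7 sites on 6 chromosomes. U6, the catalytic small nuclear RNA of the spliceosome, accounted for 98 sites at 77 loci with a median of 21.5%. The gene RNU6-9 on chromosome 19 had 82.3% (778 of 945 reads, interval 79.7 to 84.7%) in the context AAAATTGGAAC, and the pseudogene RNU6-883P on chromosome 10 had 91.2% (31 of 34 reads) in TAAAATTGGAA, which is the same sequence shifted by 1 base. The family of 7SK, a regulator of transcription elongation, had 39 sites at 22 loci, that of 7SL, the RNA of the signal recognition particle, 52 at 43, and that of the U3 small nucleolar RNA 18 at 14. U1, U2, U4 and U5 together gave few sites, with 11, 6, 6 and 1. Levels at single copies are uncertain where reads of one copy could be placed at another. Of the mitochondrially encoded genes, MT-TK had 18.2% (125 of 685 reads), MT-TL1 6.2% and MT-RNR2 5.8%.

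PUS1 and PUS7 are 2 of the 3 enzymes missing in the knockout, and the sequences that each prefers can be searched in the contexts. TRUB1, which is not among the deleted enzymes, served as a comparison. Sites were put into exclusive classes and set against 10 contexts per site with the flanking bases shuffled. The PUS7 class (UNUAR without the shared form) held 414 sites, 3.09% against 1.63% of shuffled contexts, with an odds ratio of 1.93 (interval 1.73 to 2.14, Fisher's exact test, two-sided, adjusted p = 9.9e-29). Its direction turned with the strand, with odds ratios of 3.38 on the plus strand and 0.375 on the minus strand (adjusted Fisher p = 3.64e-12). Against mirrored motifs, with any uridine of the run counted, the PUS7 ratio was 1.27 over all sites (exact binomial test, adjusted p = 7.91e-05) and 1.15 at coverage of at least 60 (adjusted p = 0.443). The TRUB1 class (GUUCNA) held 100 sites, 0.746% against 0.275%, with an odds ratio of 2.73 (interval 2.19 to 3.41, adjusted Fisher p = 1.28e-15). At coverage of at least 60 it was 5.72 (interval 3.94 to 8.29). Outside small RNA genes annotated in RefSeq, 60 sites remained (0.455%) and the TRUB1 odds ratio was 1.84 (interval 1.4 to 2.43, adjusted Fisher p = 6.98e-05). The class shared by PUS7 and PUS1 (URUAR) held 218 sites at an odds ratio of 0.927 (interval 0.806 to 1.07, adjusted Fisher p = 0.299). The PUS1 class (HRUAR without the shared form) held 312 sites at 0.686 (interval 0.611 to 0.77, adjusted Fisher p = 3.3e-11), and at a ratio of 0.772 against mirrored motifs (exact binomial test, adjusted p = 0.000186). The class with uridine on both sides (U-tract) held 31 sites at 0.0973, and at 1.61 when any uridine of the run was counted. Shuffling and mirroring both change which bases stand next to each other. How often each motif occurs at uridines of the same transcripts was not measured here. The ratios of any class, above or below 1, therefore cannot separate enzyme preference from the base order of transcripts.

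The highest members of each class are named here with their levels. In the TRUB1 class, NEIL3, a DNA glycosylase gene, had 64.5% in an intron (20 of 31 reads, interval 45.4 to 80.8%, chromosome 4 position 177338517, TCAGTTCAAAC), and the non-coding gene ENSG00000286652 had 50.3% (87 of 173 reads). In the PUS7 class, DNAJC3-DT had 60% in TGCTCTAAGGC, and MAEA, a ubiquitin ligase subunit, had 56.2% in an intron in TTTTTTAGACA (9 of 16 reads). In the PUS1 class, the pseudogene ENSG00000213750 had 73.8% (45 of 61 reads, ATACGTAGCAG) and RAB30-DT 52.4% (22 of 42 reads, GTACATAGCCG). The context of ENSG00000213750 differs only in its first base from GTACGTAGCAG, which was listed in the 28S rRNA. RAB30-DT also had a site in GGGTTTCGTAC, another context of the 28S rRNA. Whether sequence copied from ribosomal RNA lies behind these levels was not tested. In the shared class, the pseudogenes RNA5-8SP7 and RNA5-8SP4 had 92.3% and 54.7%. In the U-tract class, LHFPL6 had 53.3% (8 of 15 reads) and SNX18P10 26.7% (4 of 15 reads).

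Class membership depended on where in a run of uridines the deletion had been placed. A deletion in such a run cannot be assigned to one base, and 58.7% of the sites lay in a run of at least 2. As listed, the TRUB1 class held 95 sites on the plus strand and 5 on the minus strand, and the PUS7 class 373 and 41. With any uridine of the run counted, TRUB1 sites numbered 101 on the plus strand and 108 on the minus strand, 209 in all, at an odds ratio of 3.03 (interval 2.59 to 3.54, adjusted Fisher p = 1.24e-35), and at 2.03 outside small RNA genes (interval 1.69 to 2.45). The PUS7 class then held 443 and 201 sites, so that its strands stayed unequal, and 644 in all at 1.29 (interval 1.19 to 1.4, adjusted Fisher p = 1e-08).

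**Figure D3:**
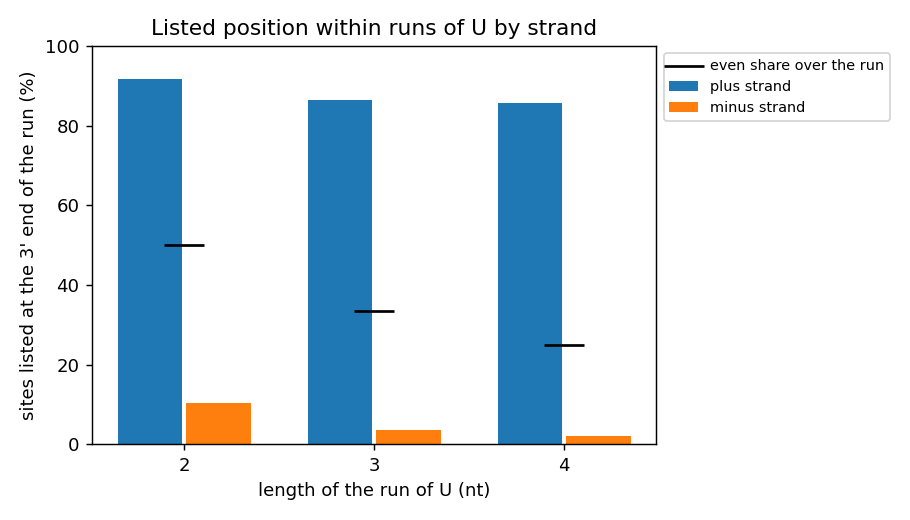
Share of sites listed at the 3' end of their run of uridines (y axis, percent), for runs of 2, 3 and 4 nt (x axis), with one bar per strand and a line at the share that even placement gives. On the plus strand 91.7% of sites in runs of 2 stood at the 3' end, and on the minus strand 10.3%.

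**Figure D4:**
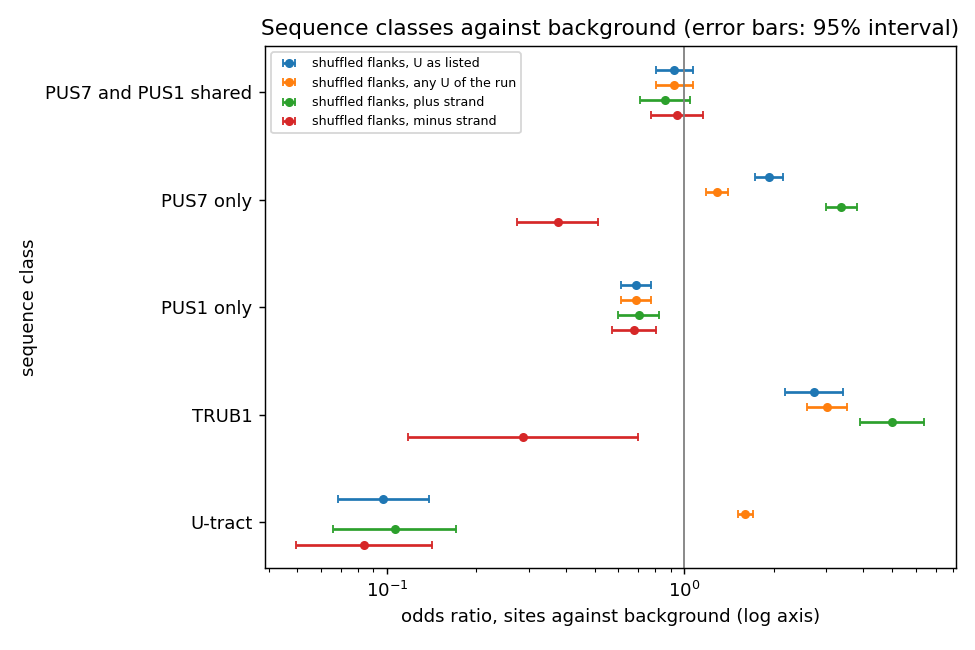
Odds ratio of each sequence class (x axis, log scale) at the sites against background, with points for the estimate and bars for the 95% interval, under 4 combinations of placement and strand. TRUB1 was at 5.0 on the plus strand and 0.287 on the minus strand as listed, and at 3.03 with any uridine of the run.

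The TRUB1 motif was also the motif that became more frequent at sites with more deletion reads, in a comparison chosen after seeing the data. Among protein-coding sites with any uridine of the run counted, it stood at 0.835% of the 3953 sites with 3 deletion reads, at 2.17% of the 968 with 8 to 15, and at 13.5% of the 89 with 16 or more (interval 7.17 to 22.4%). The last share includes sites inside RefSeq tRNA genes, among them those named CFAP418 (54 deletion reads) and KNL1 (42), and was not computed without them. With at least 8 reads against 3, the odds ratio was 3.83 (interval 2.35 to 6.23, Fisher's exact test, two-sided, adjusted p = 1.26e-06). Outside small RNA genes annotated in RefSeq it was 2.72 (interval 1.57 to 4.72, adjusted Fisher p = 0.00227). The same comparison gave 0.846 for the PUS7 class (adjusted Fisher p = 0.524), 0.797 for PUS1 (adjusted p = 0.524) and 1.08 for the shared class (adjusted p = 0.777). The 33 TRUB1 sites with at least 8 deletion reads, named here after their values were seen, included ERH, a small conserved nuclear protein, with 13.2% in its 3'UTR (144 of 1091 reads, interval 11.2 to 15.4%, chromosome 14 position 69380271, GTTGGTTCCAG). IDI1, an isoprenoid synthesis enzyme, had 17.9% in an exon (26 of 145 reads), and PABPC4, a poly(A) binding protein, 14.7% (24 of 163 reads). Of the 33, 11 lay inside RefSeq tRNA genes. Over the whole map, 86 sites lay inside tRNA genes and 75 of these carried the motif, which is that of the T loop of tRNA.

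**Figure D5:**
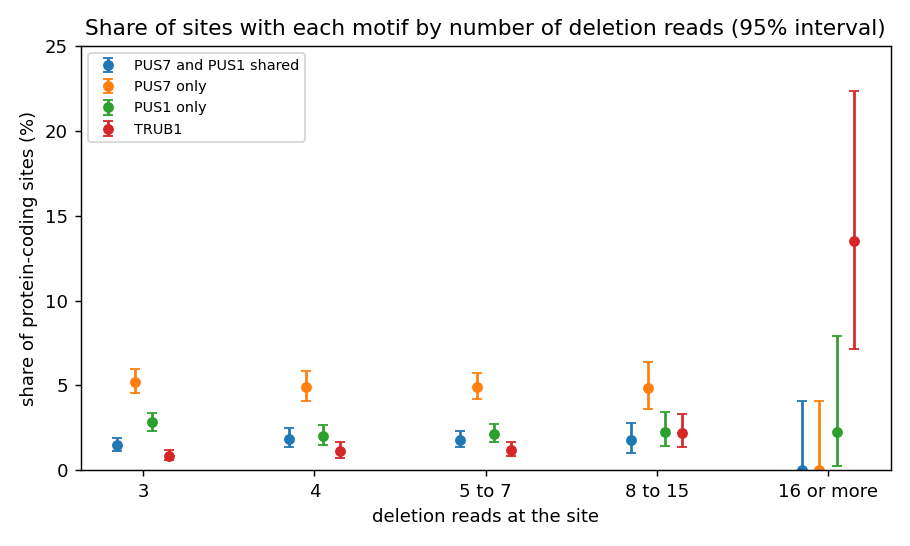
Share of protein-coding sites (y axis, percent) that carry each motif at any uridine of the run, by the number of deletion reads at the site (x axis), with 95% intervals. The TRUB1 share was 0.835% at 3 reads and 13.5% at 16 or more, while the PUS7 share was 5.21% at 3 reads, 4.86% at 8 to 15 and 0 of 89 sites at 16 or more (interval 0 to 4.06%). Sites inside RefSeq tRNA genes are included.

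Level differences between the classes changed with the depth of the sites. The PUS7 class had a median of 13.6% against 12% at other sites (permutation test, two-sided, 100000 resamples, adjusted p = 0.0119), and at coverage of at least 60 the difference was 0.1 points (adjusted p = 0.932). The TRUB1 class had 13.1% against 12% (adjusted permutation p = 0.302). At coverage of at least 60 it had 11.7% against 6.7%, a difference of 4.95 points (adjusted permutation p = 5e-05), and among sites past a 1% background it was lower by 3.8 points (a difference of -3.8, adjusted p = 0.0385). The 86 sites inside RefSeq tRNA genes, 75 of them with the motif, had a median coverage of 70 and a median level of 12.65%. Levels of the TRUB1 class outside small RNA genes were not computed, so how far the 4.95 points rest on tRNA was not tested. The shared class had 10.5%, the PUS1 class 11.5% and the U-tract class 9.8%, with adjusted permutation p of 0.0882, 0.302 and 0.302. Sites within one transcript are not independent replicates.

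Intronic sites were listed at higher levels than exonic ones, with medians of 14.0% and 9.3%, a difference of 4.7 points (permutation test, two-sided, p = 1e-05, the smallest the resamples can give). The difference was 0.2 points at coverage of at least 60 (6.7% against 6.5%, permutation p = 0.0253). Intronic sites in protein-coding genes lay more often among pyrimidines than exonic ones, but 3'UTR sites did so too: 21.1% (interval 20.1 to 22.2%) had at least 8 pyrimidines among the 10 flanking bases, against 9.92% of exonic sites (interval 8.59 to 11.4%) and 16.7% of 3'UTR sites (interval 14.9 to 18.6%). Mean pyrimidine content of the flanks was 55.5% at intronic, 50.0% at exonic and 55.6% at 3'UTR sites. Pyrimidine content of introns in general was not measured here.

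The series title links reading of pseudouridine to splicing, and the lists fixed before the data were examined open with splicing factors. Of 63 splicing regulators, 44 had a site (69.8%), with 121 sites in all, 77 of them intronic, at a median of 12.5%. This compares with 10.3% of all other RefSeq genes (odds ratio 20.2, interval 11.8 to 34.6, Fisher's exact test, two-sided, adjusted p = 3.33e-28) and with a median of 25.4% in random lists matched on gene length (adjusted p = 0.0006, from the smallest p the lists can give). QKI, an RNA-binding regulator of splicing, had 81.2% in an intron (13 of 16 reads, interval 54.4 to 96.0%, chromosome 6 position 163415925). CELF1, which binds GU-rich RNA, had 76.4% in its 3'UTR, RBFOX2 56.2% in an intron (9 of 16 reads), and SRSF12, an SR protein, 47.1% in an exon (8 of 17 reads). Of 60 core spliceosome and Sm or LSm genes, 27 had a site (45%, odds ratio 7.11, adjusted Fisher p = 1.71e-11, and 2.06 with adjusted p = 0.203 for sites with levels of at least 20%), against 23.3% in length-matched lists (adjusted p = 0.0009). The highest was in an intron of TXNL4A, a U5 particle protein, with 33.9% (642 of 1893 reads), in GGGTTTCGTAC, a context also listed in the 28S rRNA. The levels in QKI and CELF1 need care, because the other 3 sites of QKI and the other 2 of CELF1 were listed on the opposite strand, and the 2 sites of TXNL4A lay on opposite strands. Of 2426 protein-coding genes with at least 2 sites, 273 (11.3%) had sites on both strands, a count made after seeing the data, so a gene name can mark a locus and not the transcript read. PRPF4 had 25% (5 of 20 reads) and AQR, an intron-binding helicase, 21.1% (4 of 19 reads), both in introns.

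Genes of translation and growth were listed often as well. Translation factors had sites in 36 of 70 genes (51.4%, odds ratio 9.21, adjusted Fisher p = 3.24e-17, length-matched 24.3%), with 47.4% in an intron of EIF2B3 and 40.6% near the promoter of EIF4G1, the scaffold of the cap-binding complex. Cytoplasmic ribosomal proteins had sites in 33 of 88 (37.5%, odds ratio 5.22, adjusted Fisher p = 3.05e-11, length-matched 11.4%), but with levels of at least 20% in only 3 (odds ratio 1.02, adjusted p = 0.771), led by RPL13 with 38.9% in an intron (7 of 18 reads) and RPS27 with 21.1% in an exon (12 of 57 reads). Cell cycle and replication genes had sites in 22 of 44 (50.0%, odds ratio 8.68, adjusted Fisher p = 6.41e-11, length-matched 25%), with 38.5% in POLE, a DNA polymerase, and 25% in each of CDK6, MCM6 and ORC2. Cancer genes had sites in 21 of 40 (52.5%, odds ratio 9.6, adjusted Fisher p = 6.2e-11), closer to the 35.0% of length-matched lists (adjusted p = 0.0402). NF2 had 60% (9 of 15 reads) and NOTCH2 59.1% (13 of 22 reads).

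Pseudouridine synthases were not listed more often than other genes: 2 of 13 had a site (odds ratio 1.57, interval 0.349 to 7.1, adjusted Fisher p = 0.708), PUS7L with 31.6% (6 of 19 reads) and PUS7 with 10.0% (4 of 40 reads). Histone genes had sites in 5 of 188 (odds ratio 0.236, adjusted Fisher p = 0.000127), with 70.0% at H3C4 (14 of 20 reads), and among the 94 that code for protein 3 had a site, against 5.32% in length-matched lists (adjusted p = 0.618). The list of small structured RNAs and snoRNA hosts had sites in 211 of 3430 members (6.15%, odds ratio 0.552, adjusted Fisher p = 3.72e-18). Mitochondrially encoded genes had sites in 3 of 37 (odds ratio 0.764, adjusted Fisher p = 1), and none of the 13 that code for protein had one (odds ratio 0.107 among protein-coding genes, adjusted p = 0.0313). These 13 are short, and random lists matched on length also had a median of 0 genes with a site. Part of these odds ratios came from the non-coding genes in the comparison. Among protein-coding genes alone they were 6.75 for splicing regulators, 2.38 for core spliceosome genes, 3.08 for translation factors, 1.74 for ribosomal proteins, 2.9 for cell cycle genes and 3.21 for cancer genes, each with an adjusted p under 0.05 (Fisher's exact test, two-sided). Expression was not matched in these comparisons, and a gene must be expressed to reach 15 reads at a site.

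The comparison that the design text names, treated control against treated knockout cells, could not be made from pooled values, nor could the comparisons of treated with untreated libraries, of HEK293T with HuCCT1, or of replicates with each other. How many of the listed sites fell in cells lacking PUS1, PUS7 and RPUSD4 was not analysed here.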

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

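Of 111 alternatives with settings fixed before the data were examined and free to differ from the main value, 79 were counted as the same. Those of the sequence classes were run on the shuffled background, which was itself chosen after the data had been seen. Of 90 chosen after seeing the data, 59 were. For tested results this means the same direction and call, not the same size. The intronic minus exonic difference of 0.2 points at coverage of at least 60, against 4.7, counts as the same. A further 22 and 2 equal the main value by construction and are not counted: one site per gene and merging of close sites keep the genes with a site, and the shared and PUS1 motifs fit only a single uridine. No paired analysis was possible because the columns carry no library. Alternatives that leave out a replicate, subtract untreated levels, use knockout or HuCCT1 values, need splice site distances or need a count of introns could not be run, and the cause of the changes below was not tested except where stated. Depth limits every level, since the lowest level that can be listed falls with coverage up to 60 reads.

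The median level of 12% was 10.3% at coverage of at least 20 and 6.7% at 60, and by construction 16.7% and 25% with levels of at least 10% and 20%. It was 20% among the 5021 sites that passed a binomial test against a 1% background. All 13398 passed at 0.1%. With levels of at least 10% the shares were 58.8% intron, 13.2% exon, 10.3% 3'UTR, 2.02% termination and 0.792% 5'UTR, and with at least 20% they were 63.9%, 10.3%, 8.46%, 1.29% and 0.627%. One site per gene gave 47.4% intron, 10.7% promoter and 7.31% intergenic. Coverage of at least 60 gave 28.7% intron, 28.6% exon, 16.1% 3'UTR, 13.9% promoter, 7.42% intergenic, 3.99% termination and 1.28% 5'UTR. Past a 1% background the shares were 53.3%, 15.3%, 10.5%, 10.7%, 7.13% and, for the 5'UTR, 0.836%.

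Of the class odds ratios, the shared class turned from 0.927 to 1.04 with runs of the same length, 1.02 at coverage of at least 60, and 1.02 against mirrored motifs, none with a call. Neighbouring uridines as background gave 1.42 for the shared class and 4.96 for PUS1, which is no evidence of a turn, since the site's own uridine bars these motifs at most neighbours. On the minus strand, PUS7 turned to 0.375 and TRUB1 to 0.287, both with a call. With any uridine of the run counted the TRUB1 strands evened out and those of PUS7 did not. U-tract turned, with a call as well, to 1.61 with any uridine of the run, and to 1.57 when small RNA genes were also left out.

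Level differences between a class and other sites, in points, moved as follows. The shared class turned from -1.5 to 0.2 (level of at least 10%), 0.3 (one site per gene) and 0.1 (coverage of at least 60). PUS7 lost its call at 0.7 (level of at least 10%), 0.724 (means), 0.1 (coverage of at least 60) and 1.1 (past a 1% background). PUS1 turned from -0.55 to 0.5, 1.9 (one site per gene), 0.113 (means) and 0.95 (coverage of at least 60). TRUB1 turned from 1.1 to -0.5 (one site per gene) and -3.8 (past a 1% background), and gained calls in opposite directions, at 4.95 (coverage of at least 60) and at the -3.8. U-tract turned from -2.2 to 0.7, 2.4 (one site per gene) and, with a call in the opposite direction, 1.1 (any uridine of the run, adjusted permutation p = 0.00065). The intronic minus exonic difference kept its direction and call in all 5 alternatives, from 0.2 to 6.8 points.

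With levels of at least 20%, core spliceosome genes (odds ratio 2.06) and ribosomal proteins (1.02) lost their calls. Pseudouridine synthases turned to 0.526 among protein-coding genes and to a ratio of 0.667 when matched on length. Mitochondrial genes passed the threshold at 0.107 among protein-coding genes and turned to 1.62 past a 1% background. When matched on length they had no call, since the random lists also had a median of 0 genes with a site. Histones lost their call when matched on length, at a ratio of 0.6. The remaining lists kept their calls.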

Other observations

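All tests in this part were chosen after the result was seen. Contexts shaped like splice sites were listed in introns more often than shuffled flanks gave. With the site at the U of GGURAG, the shape of a 5' splice site, 39 of 6826 intronic sites (0.571%) stood against 0.234% of shuffled contexts (odds ratio 2.45, interval 1.72 to 3.47, Fisher's exact test, two-sided, p = 5.01e-06) and 2 of 2361 exonic sites. ABCC1 had 50.0% there (11 of 22 reads, AGAGGTAAGTG). With 5 pyrimidines followed by UAG, the shape of a 3' splice site, 45 intronic sites (0.659%) stood against 0.209% of shuffled contexts (odds ratio 3.16, interval 2.26 to 4.42, adjusted Fisher p = 3.93e-09), with 55.0% in USP9X (11 of 20 reads, TTTTCTAGGCC) and 34.2% in LEMD3 (13 of 38 reads, TTTTTTAGGCA). The difference between introns and exons for this shape had an odds ratio of 1.95 (interval 0.919 to 4.15, Fisher p = 0.0833). Of the 251 intronic sites of the PUS7 class, 35 had this shape. Of the 45 intronic sites, 37 lay on the plus strand and 8 on the minus strand. In runs of 2 to 4 uridines, 88.9% of plus-strand sites were listed at the 3' end, which leaves uridines before the site. Shuffled flanks do not model this placement, so the odds ratio of 3.16 cannot separate a splice site shape from placement. Whether these sites lie at annotated splice sites was not analysed here.

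The deepest intronic sites of protein-coding genes carried contexts of structured RNAs. Of the 13 with coverage of at least 1000, 9 had an 11-nt context that was also listed at a structured RNA, against 49 of 5898 with less coverage (Fisher's exact test, two-sided, p = 3.06e-16). They include RYR2 (30.1%, 3590 of 11927 reads, GAGCTTGACTC), AAMDC (7.3% in the same context), USP13 (27.8%, GTACGTAGCAG) and TXNL4A (33.9%), whose contexts were listed in ribosomal DNA, and VPS13B (12.2%, AAGTTTCTCTG), whose context was listed at U3. Only identical contexts were counted, so 9 is a minimum. SLCO5A1 (43.5%, 4888 of 11236 reads) had TGAGCTTGACT, which is GAGCTTGACTC shifted by 1 base. A further RYR2 site (CCTACTATCCA) and HFM1 (TTGGGTTTTAA) had contexts that overlap TACTATCCAGC and GGTTTTAAGCA of the 28S rRNA. Of pairs of sites 1 nt apart, 420 of 771 had the same deletion reads and coverage.

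In runs of 2 to 4 uridines, the listed base was nearly always the one at the end with the higher genome coordinate. This held at 5627 of 6403 sites, or 87.9%, a value consistent with placement of ambiguous deletions by genome coordinate. An enzyme preference for one end of the run in the RNA would put both strands at the same end. On the plus strand 88.9% of sites stood at the 3' end of the run in the RNA and on the minus strand 6.6%, which argues against it. Which uridine of a run is modified stays open.

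Most p-values in the authors' deposited table are exactly 0, even at 228 sites with 3 deletion reads in 15. Of the 133 p-values above 0 with an implied control rate of over 1 deletion in 1000 reads, 82.0% gave a whole number of reads per control deletion within 0.01, where chance gives 2.0%. This is consistent with a binomial test in which the rate is taken from control reads, so that a p-value of 0 may mean that the control reads held no deletion. Rounding of very small p-values to 0 is argued against, since at 98.9% of the sites at 0 a control rate of 1e-06 would have left a p-value above 0. The highest implied rate was 1.04%, and the libraries behind the control rate stay open.

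The higher level of intronic sites is a candidate effect of the minimum of 3 deletion reads at lower intronic coverage. The difference of 4.7 points fell to 0.2 points at coverage of at least 60, where the minimum is even. A higher level in introns at equal coverage is argued against as the main source: averaged within 5 bands of coverage, each weighted by its numbers of intronic and exonic sites (their product over their sum), the difference was 0.575 points. It was 0.0 at 15 to 19 reads, 1.0 at 20 to 29, 0.7 at 30 to 59 (2554 intronic and 992 exonic sites, permutation test, adjusted p = 2.5e-05), -0.1 at 60 to 119 and 1.9 at 120 or more (137 and 130 sites, permutation test, adjusted p = 2.5e-05). The 137 intronic sites of the last band include ribosomal RNA positions that were deposited as intronic, while other ribosomal RNA positions were deposited as exonic. Of the 13 intronic sites of protein-coding genes with coverage of at least 1000, at least 9 had a context listed at a structured RNA. Differences without these sites were not computed, so the 1.9 points cannot separate introns from structured RNA. The same sites enter the 0.2 and 0.575 points. A smaller difference at equal coverage stays open, as at 30 to 59 reads, and its source was not tested. No biological explanation could be tested on groups of samples.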
